A study of Mus musculus with 2 samples.

How the data were processed

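Single-cell RNA sequencing was performed by the authors on cornea and limbus of mice with the 10x Genomics system. Per the labels, lens, retina, iris and trabecular meshwork were removed and most of the conjunctiva was dissected away. The tissue was digested in 0.7 mg/mL liberase for 1 h at 37 °C and in 0.25% trypsin for 15 min, and the suspension was passed through a 40 µm filter. Suspensions with a viability of at least 80% were used. The series description names 2 wild-type and 2 Pax6 heterozygous mice, but the files hold 1 library per genotype, and the labels do not say whether mice were pooled. Sex, age, strain and the Pax6 allele are not given.

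Each deposited matrix holds counts, which are raw unique molecular identifiers (UMIs) per gene and cell barcode with no normalization. Per the file headers the matrices were made with Cell Ranger 8.0.0, and the submitters' notes give the GRCm38 build. Both libraries list the same 32285 genes. The wild-type library held 124540296 UMIs in 11354 barcodes and the library labelled Pax6 heterozygous held 131567589 UMIs in 10574 barcodes. The lowest barcode total was 500 UMIs in each, so barcodes had been selected before deposit by a rule that is not stated. Gene positions were looked up by Ensembl identifier in the GENCODE annotation of the same build.

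Cells with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept. Scrublet, run in each library through scanpy, marked 2 of the wild-type cells (0.020%) and 22 of the heterozygous cells (0.231%), and these were removed. A caller that marks so few cells has not worked, so most doublets are expected to remain. After filtering, 10152 wild-type and 9520 heterozygous cells were left, with medians of 10216 and 12516 UMIs per cell. Both libraries were scaled to 10000 UMIs per cell, log-transformed and clustered together without integration, on 2000 variable genes, 30 principal components and 15 neighbours, with the Leiden algorithm at resolution 1.0. Epithelial cells were then clustered again in the same way.

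Clusters were named from fixed marker genes. A broad name needed at least 3 markers at 20 CPM or more (UMIs scaled to a common class total) and at 0.25 or more of the level in the highest cluster. An epithelial subcluster name needed at least 3 markers at least 1.5-fold above all other epithelial cells. A limbal-like name also needed Gpha2 among them, and a corneal-like name needed Krt12 at 0.25 or more of the pooled epithelial level. Clusters with a median depth under 0.333 of their own library's and no own marker among their 10 leading genes stayed unnamed. These naming thresholds were set after the data were seen, whereas the markers were not. Each named cluster was checked for markers of another class among its 10 leading genes by fold.

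For each class, UMIs were summed per library and expressed as CPM over the class total without mitochondrially encoded genes. Ratios are the library labelled Pax6 heterozygous over wild type. With 1 library per genotype no test, p-value or standard error could be given. Intervals are exact 95% intervals, conditional binomial for ratios and Clopper-Pearson for shares, and cover counting error only, not differences between mice, dissections or libraries. Genes with at least 20 CPM in either library were counted as at least 2-fold higher or lower by size alone. A count of 0 was set to a floor of 3 UMIs to give a lower bound. Cells of blood and lymphatic vessels, mural cells, Schwann cells and immune cells, 266 in the wild-type and 1420 in the heterozygous library, served as reference cells. Their level of an epithelial gene shows how much free RNA from lysed cells could add. Their median depths of 3521 and 6340 UMIs were below the 11575 and 14022 of epithelial cells. An equal amount of free RNA would therefore weigh more in their CPM, so this level may overstate free RNA in deeper cells.

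The 29 gene lists compared were: limbal, basal epithelial, corneal differentiation, conjunctival, epidermal, wound and stress keratin, cell cycle, cell cycle inhibitors, hemidesmosome and basement membrane, desmosome and cell junction, Notch, Wnt, Eph and ephrin, autophagy, immediate early and dissociation stress, interferon response, antigen presentation, chemokines and inflammation, glycolysis, oxidative phosphorylation, antioxidant, cytosolic ribosomal proteins, cholesterol and lipid synthesis, TGF-beta with BMP and EMT, p53 and apoptosis, keratocyte matrix, myofibroblast and fibrosis, angiogenic factors, and Pax6-related eye regulators. Another 3 lists served as checks: sex-linked, haemoglobin and mitochondrially encoded genes. A list's median log2 ratio was taken over members with at least 5 CPM in either library. It was placed as a percentile among 10000 random lists of equal size drawn within 20 expression bins, as a description of these libraries and not a test.

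Genes were named by a rule. Among genes with at least 50 CPM in either library, without mitochondrial and 6 sex-linked genes, these were the 12 with the highest lower interval bound and the 12 with the lowest upper bound in the epithelial class and its parts, and 5 each way in other classes. Added to them were Pax6 and up to 3 members of each list with at least 20 CPM, which were the most abundant and those with the highest and the lowest ratio. Predicted genes were counted rather than named. Any other gene that is named was chosen after its values were seen. Non-epithelial classes were compared only with at least 100 cells in each library, which left the keratocytes.

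Markers, gene lists, filters, comparisons, the rule for naming genes and the first set of alternatives were chosen before the data were examined. The corneal-like comparison, the keratocyte comparison restricted to library-specific clusters, the restriction of class gene values to subclusters that passed the marker check, the count of cells with little Krt12 and 4 further alternatives were added after seeing the data. Cycling cells were counted as those with at least 2 UMIs over Mki67, Top2a, Birc5, Ube2c, Cdk1 and Ccnb1 after each cell was thinned to 3000 UMIs. Shallower cells were left out of that count. The alternatives covered cell filters, doublet removal, clustering, the scaling of sums with edgeR TMM or DESeq2 factors, equal weighting of cells, expression minimums and the cycling definition.

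The pipeline was tested on simulated data made from the wild-type epithelial sums. All 50 genes at each of 4 simulated folds were found at least 2-fold apart, 0 of 3041 unchanged genes were, and 94.9% of the unchanged genes' intervals held the true ratio. The simulation held counting noise only, with no difference between mice, dissections, cell mixes or free RNA. It checks the calculation and says nothing on how many genes would differ between 2 real libraries. Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.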

Results

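Single-cell transcriptomes were collected from the cornea and limbus of wild-type mice and of mice labelled Pax6 heterozygous, with 1 library per genotype. Pax6 encodes a transcription factor of eye development that the corneal epithelium keeps expressing in the adult. The comparison asks how a reduced dose of Pax6 alters the cells of the anterior segment, the limbal epithelium that holds the corneal stem cells in particular. The wild-type library gave 10152 kept cells with a median of 10216 UMIs and 3316 genes, and the library labelled Pax6 heterozygous gave 9520 kept cells with a median of 12516 UMIs and 3760 genes. There were no replicates, so "higher" and "lower" describe these 2 libraries, and each interval covers counting error only.

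Pax6 itself was higher in the library labelled Pax6 heterozygous. In epithelial cells Pax6 (ENSMUSG00000027168; GRCm38 chromosome 2, 105668900 to 105697364, plus strand) stood at 369 CPM in the wild-type library and at 761 CPM in the heterozygous library, a ratio of 2.06 (95% interval 2.04 to 2.09). Within corneal-like cells alone it stood at 356 and 819 CPM, a ratio of 2.30 (2.24 to 2.37), which came from subcluster 24 (1698 CPM, 224 cells) and not from subcluster 19 (366 CPM, 239 cells). Reference cells, which should lack Pax6, held 125 and 52.9 CPM. A UMI count does not separate the mutant from the normal transcript, and the labels do not describe the allele. The libraries also differed in sex: Xist without any Y-linked UMI was found in 94.6% of wild-type and 46.3% of heterozygous cells, and Y-linked UMIs without Xist in 0 wild-type and 3750 heterozygous cells (39.4%). The wild-type library was thus female and the heterozygous library a mixture of both sexes.

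The cell composition of the libraries differed, with fewer epithelial cells and more vessel and nerve-associated cells in the library labelled Pax6 heterozygous. Epithelial cells made up 82.1% (81.4 to 82.9) of the wild-type and 71.5% (70.5 to 72.4) of the heterozygous library, 8337 and 6803 cells. Keratocytes, the stromal cells that make the corneal matrix, made up 6.44% (5.97 to 6.94) and 10.3% (9.71 to 10.9), but only 4.72% (4.11 to 5.39) of heterozygous cells with Xist and no Y-linked UMI. Mural cells, which wrap small vessels and were named from markers such as Rgs5 and Myh11, made up 0.552% (0.417 to 0.716) and 5.54% (5.08 to 6.01). Blood and lymphatic vessel cells together with mural cells came to 151 wild-type cells, or 1.49% (1.26 to 1.74), and to 1016 heterozygous cells, or 10.7% (10.1 to 11.3).

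The vessel cells were of both kinds. Vascular endothelial cells, led by Selp and Flt1, made up 0.798% of the wild-type and 3.29% of the heterozygous library, and lymphatic endothelial cells, led by Lyve1 and Prox1, made up 0.138% and 1.85%. Schwann cells, the glia of peripheral nerve, made up 0.739% and 2.93%. A cluster named dendritic, whose 10 leading genes held 3 dendritic and 3 macrophage markers, made up 0.355% and 1.10%, and T or NK cells 0.0394% and 0.210%. Unnamed clusters held 8.82% of the wild-type and 3.31% of the heterozygous cells, at medians of 2138 and 1564 UMIs. The largest of them held 833 wild-type and 14 heterozygous cells and was led by Gm42418 and Lars2, and the next held 2 and 284 cells and was led by genes that included Gpha2 and Pclaf. Among heterozygous cells with Xist and no Y-linked UMI the epithelial share was 80.6%, which is -1.54 percentage points from the wild type (interval -3.48 to 0.377) in place of -10.7 (-12.3 to -9.00). That filter was not applied to the wild-type cells, so part of this narrowing may come from the unequal filter. Of the 9601 wild-type cells that would pass it, 8119 were epithelial, beside 8337 of all 10152. How much limbus and conjunctiva each dissection left behind also sets these shares, and it is not recorded.

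**Figure D1:**
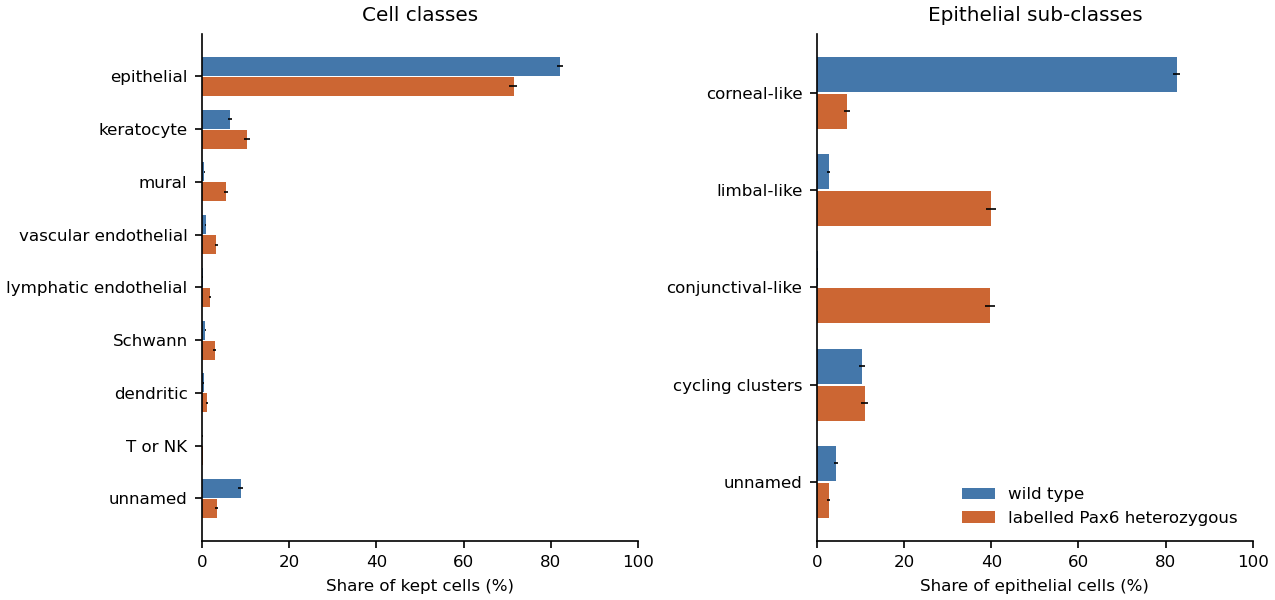
Horizontal bars give each class as a percentage of kept cells (left) and each sub-class as a percentage of epithelial cells (right) in the wild-type library and in the library labelled Pax6 heterozygous, 1 library each, with 95% exact binomial intervals as black lines. Epithelial cells made up 82.1% and 71.5% of kept cells, and limbal-like cells 2.71% and 39.9% of epithelial cells.

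In the epithelium, most cells held little or none of the corneal keratin transcript in the library labelled Pax6 heterozygous. Krt12 (ENSMUSG00000020912; chromosome 11, 99415666 to 99422259, minus strand), which encodes the main keratin of the corneal epithelium, stood at 29350 CPM in the wild-type and at 1781 CPM in the heterozygous library, a ratio of 0.0607 (0.0604 to 0.0610). The median cell held 247 Krt12 UMIs per 10000 in the wild-type library and 0 in the heterozygous library. Fewer than 20 per 10000 were held by 184 of 8337 wild-type cells (2.21%) and by 6193 of 6803 heterozygous cells (91.0%). The range around that limit, from 10 to 40 per 10000, held 145 and 131 cells. Reference cells held 4522 and 46.0 CPM of Krt12, so free Krt12 RNA was far more abundant in the wild-type suspension.

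**Figure D2:**
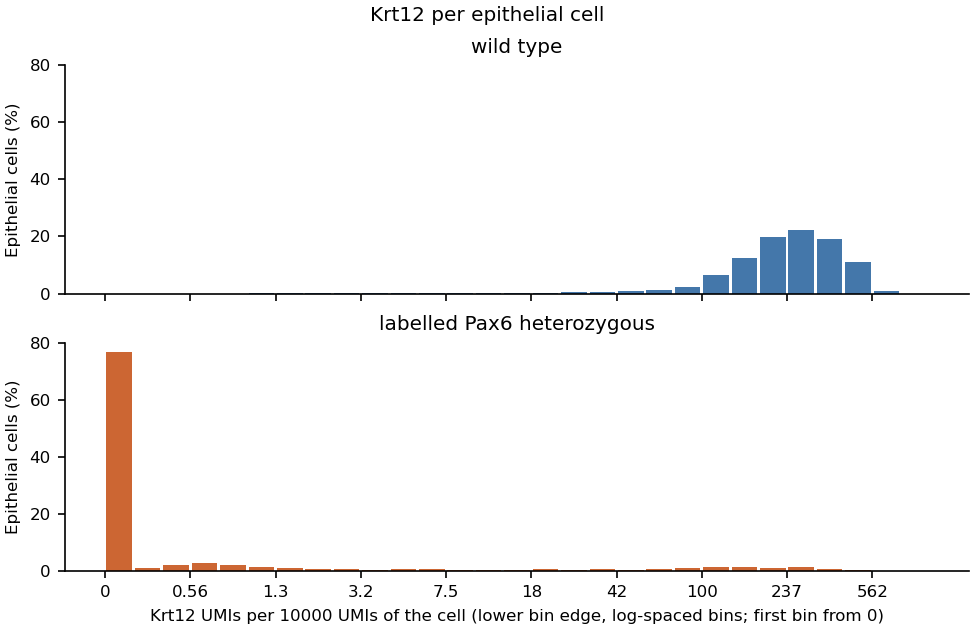
Histograms give the percentage of epithelial cells (y axis) by Krt12 UMIs per 10000 UMIs of the cell (x axis, log-spaced bins, the first from 0), for 8337 wild-type cells above and 6803 cells of the library labelled Pax6 heterozygous below. The medians were 247 and 0 per 10000.

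Other genes of corneal differentiation were lower too. Of the 15 measured genes of the corneal differentiation list, 0 were at least 2-fold higher and 9 at least 2-fold lower in the heterozygous library, with a median log2 ratio of -1.44, at percentile 0.0 of random lists. Slurp1, a secreted anti-inflammatory protein of the ocular surface, stood at 2794 and 27.3 CPM, a ratio of 0.00976. Aldh3a1, the crystallin-like aldehyde dehydrogenase of the cornea, stood at 10730 and 2649 CPM, the water channel gene Aqp5 at 4725 and 557 CPM, and transketolase (Tkt) at 5659 and 1289 CPM. The transcription factor gene Klf5 had the highest ratio of the list, at 294 and 477 CPM. In the wild-type reference cells Slurp1 held 380 CPM and Aldh3a1 2051 CPM, below their epithelial levels.

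Desmosome and cell junction genes were lower as well. Of 19 desmosome and cell junction genes, 0 were at least 2-fold higher and 5 at least 2-fold lower (median log2 ratio -0.58, percentile 0.0). Desmoplakin (Dsp), which anchors keratin filaments at desmosomes, stood at 2300 and 933 CPM, and the desmosomal cadherin gene Dsg1a at 273 and 9.98 CPM, while Dsg2 stood at 53.1 and 76.0 CPM. Of 14 hemidesmosome and basement membrane genes, 2 were at least 2-fold higher and 1 lower. The hemidesmosome collagen gene Col17a1 stood at 1296 and 597 CPM, and Col4a6 at 9.03 and 71.6 CPM. That list's median log2 ratio was 0.11 and changed sign under edgeR (-0.22) and DESeq2 (-0.23) factors.

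Keratins and secreted proteins of conjunctiva and of wounded epithelium were higher. Of 9 measured conjunctival genes, 7 were at least 2-fold higher and 1 lower, with a median log2 ratio of 3.19 (percentile 100). Krt7, a simple-epithelial keratin, stood at 4.68 and 229 CPM, Krt19 at 30.1 and 340 CPM, and Krt4, a keratin of mucosal epithelium, at 54.4 and 894 CPM. Lypd2 was the 1 member at least 2-fold lower, at 4199 and 165 CPM. Of 8 wound and stress keratin genes, 5 were at least 2-fold higher and 1 lower (median log2 ratio 3.20, percentile 100). Krt17, a keratin of injured and activated epithelium, stood at 18.8 and 1201 CPM and the antimicrobial lipocalin gene Lcn2 at 0.232 and 64.2 CPM, whereas Krt6a stood at 1904 and 1020 CPM and Krt6b at 1522 and 592 CPM. Of 4 measured epidermal genes, 1 was at least 2-fold higher, with Sprr1a at 149 and 192 CPM and Krt10 at 23.1 and 28.2 CPM, and the list's median of 0.33 fell to 0.01 under edgeR and changed sign under DESeq2 factors.

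Limbal markers did not move together. Gpha2 (ENSMUSG00000024784; chromosome 19, 6226380 to 6227768, plus strand), a glycoprotein hormone subunit expressed in limbal epithelium, stood at 76.1 and 329 CPM in epithelial cells, a ratio of 4.33 (4.22 to 4.43). Krt15 (ENSMUSG00000054146; chromosome 11, 100131758 to 100135928, minus strand), a keratin of basal progenitor cells, stood at 2157 and 10700 CPM, a ratio of 4.96 (4.94 to 4.98). By subcluster it was highest in the mostly heterozygous conjunctival-like subclusters 16, 17, 20 and 21 (22692, 11613, 17675 and 11273 CPM). Heterozygous limbal-like subclusters 11 and 22 held 3941 and 3787 CPM, so its higher level was not particular to limbal-like cells. Wild-type suprabasal-like subclusters 1 and 7 held 6882 and 5558 CPM, and limbal-like subcluster 9 held 5147 CPM. Cd63 stood at 9.26 and 237 CPM and Ifitm3 at 68.2 and 1169 CPM, while the transporter gene Abcg2 stood at 34.7 and 1.73 CPM, below its reference levels of 300 and 241 CPM as Cd63 was (452 and 754 CPM), and the metallothionein gene Mt2 at 773 and 281 CPM. Of the 11 measured limbal genes, 4 were at least 2-fold higher and 2 lower, and the median log2 ratio was -0.43 (percentile 1.8). It was -0.75 with edgeR and -0.76 with DESeq2 factors.

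Cells that resembled the limbal epithelium were a small part of the wild-type and a large part of the heterozygous epithelium. Limbal-like cells made up 2.71% (2.37 to 3.08) of wild-type and 39.9% (38.7 to 41.1) of heterozygous epithelial cells, 226 and 2715 cells. With clustering that left out the limbal genes and Pax6, the shares were 2.94% and 43.0%, though the subclusters were still named from the limbal markers. With each library clustered alone they were 2.59% and 24.8%. Without the 5% highest doublet scores they were 0.0126% and 43.2%, because the wild-type cluster lost its name, and the Xist-only heterozygous cells had a share of 31.1%. The limbal-like cells of the libraries fell into different subclusters: 225 of the wild-type cells were in subcluster 9, and 1232 and 1397 of the heterozygous cells were in subclusters 11 and 22. A further 86 heterozygous cells were in subcluster 12, whose leading genes held the endothelial marker Pecam1, and the share without them was 38.6%.

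The rest of the epithelium was divided differently as well, and these sizes are given only as a description because the clusters rest on genes that differed. Corneal-like cells made up 82.5% of wild-type and 6.85% of heterozygous epithelial cells, conjunctival-like cells 0.192% and 39.7%, and cycling clusters 10.2% and 10.9%. Of these, wild-type corneal-like subclusters 6 and 8 (751 and 387 cells) and heterozygous conjunctival-like subcluster 20 (837 cells) had a marker of another class and none of their own among their 10 leading genes. The heterozygous conjunctival-like subclusters 17 and 20, of 536 and 837 cells, also held 4 and 5 limbal markers. A cluster mostly of 1 library may be that library rather than a type. Cluster 17 of all cells, with 7 wild-type and 831 heterozygous cells, had the neutrophil marker S100a9 and no epithelial marker among its 10 leading genes. Without it the Pax6 ratio was 2.24, the Krt12 ratio 0.0662, the Gpha2 ratio 4.98 and the Krt15 ratio 4.46.

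Genes of interferon response and antigen presentation were higher across the heterozygous epithelium. Of 18 measured interferon response genes, 13 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.36 (percentile 100). The antiviral membrane protein genes Ifitm1 and Ifitm3 stood at 398 and 1784 CPM and at 68.2 and 1169 CPM. Of 12 antigen presentation genes, 10 were at least 2-fold higher and 0 lower (median log2 ratio 1.34, percentile 100). B2m, the invariant chain of class I molecules, stood at 119 and 944 CPM, and H2-Q4 at 16.99 and 24.8 CPM. In reference cells, which express these genes themselves, B2m stood at 1190 and 1485 CPM and Ifitm3 at 740 and 1468 CPM. Of 12 chemokine and inflammation genes, 6 were at least 2-fold higher and 4 lower (median log2 ratio 1.06, percentile 99.6), with the membrane chemokine gene Cxcl16 at 15.2 and 38.4 CPM and the cytokine gene Il18 at 113 and 32.3 CPM.

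Metabolic groups diverged. Of 19 cholesterol and lipid synthesis genes, 1 was at least 2-fold higher and 10 lower (median log2 ratio -1.02, percentile 0.0), but among limbal-like cells 2 of 18 were higher and 0 lower (0.32). The isoprenoid enzyme gene Fdps stood at 452 and 219 CPM. Of 14 glycolysis genes, 4 were at least 2-fold higher and 0 lower (median log2 ratio 0.90, percentile 100), with Gapdh at 366 and 696 CPM and Pfkp at 5.80 and 41.0 CPM. None of 22 oxidative phosphorylation genes was 2-fold apart (median log2 ratio 0.40), nor was any of 24 cytosolic ribosomal protein genes (0.43), and under edgeR factors these medians were 0.08 and 0.11. Of the mitochondrially encoded transcripts, mt-Co3 stood at 2569 and 5411 CPM and mt-Nd2 at 687 and 746 CPM.

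Genes of growth factor signalling and matrix were higher, alongside stromal transcripts. Of 15 TGF-beta, BMP and EMT genes, 7 were at least 2-fold higher and 2 lower (median log2 ratio 0.96, percentile 100). The BMP target Id1 stood at 240 and 780 CPM, the matrix protein gene Sparc at 34.5 and 171 CPM, and fibronectin (Fn1) at 133 and 32.9 CPM. Of 7 myofibroblast and fibrosis genes, 5 were at least 2-fold higher and 1 lower (median log2 ratio 2.67, percentile 100), and all 4 measured angiogenic factor genes were higher (median log2 ratio 3.43, percentile 100). The lymphangiogenic growth factor gene Vegfd stood at 1.78 and 44.2 CPM and the matrix glycoprotein gene Tnc at 0.179 and 36.3 CPM. Of 10 keratocyte matrix genes in the same epithelial cells, 7 were at least 2-fold higher and 1 lower (median log2 ratio 1.98, percentile 100), with Col1a1 at 6.29 and 61.1 CPM and Dcn at 24.5 and 81.1 CPM. Dcn stood at 56.4 and 224 CPM in the reference cells, so free stromal RNA may also have been higher in the heterozygous suspension. The mix of reference cells differed too, with 56 wild-type and 527 heterozygous mural cells, and their own Dcn was not separated from free RNA. Sparc (1619 and 4164 CPM) and Tnc (37.0 and 437 CPM) were also more abundant in reference cells, so these are not distinguished from free RNA.

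Over all genes, 931 of 7103 with at least 20 CPM were at least 2-fold higher and 453 at least 2-fold lower in the heterozygous epithelium. The genes ranked highest by the named-gene rule included Gbp2b, an interferon-induced guanylate-binding protein gene (3 wild-type and 6258 heterozygous UMIs, ratio 2275, interval 778 to 11030). With it ranked the kinase gene Dapk2 (0.393 and 107 CPM), Lcn2, Wfdc18 (0.331 and 68.9 CPM), the cytochrome P450 gene Cyp2f2 (5.36 and 810 CPM) and the carboxypeptidase gene Cpa6 (0.268 and 50.9 CPM). Adgrg6 (0.393 and 50.8 CPM), the receptor phosphatase gene Ptprz1 (1.08 and 112 CPM), the protease inhibitor gene Serpinb3a (12.01 and 955 CPM), Esp6 (0.634 and 59.6 CPM) and 2 predicted genes completed these 12. In the heterozygous library Gbp2b, Lcn2 and Adgrg6 were higher in reference cells (221, 71.4 and 76.3 CPM) than in the epithelium, so that comparison does not distinguish these from free RNA. The wild-type reference cells held 0, 26.9 and 60.6 CPM of them, beside 0.0268, 0.232 and 0.393 CPM in the wild-type epithelium. Little of the Lcn2 and Adgrg6 RNA thus reached the epithelium of that library. Next to Slurp1, the lowest ratios were those of the adhesion gene Lsamp (668 and 9.78 CPM), the mechanosensitive channel gene Piezo2 (204 and 3.14 CPM), Nav3 (108 and 2.04 CPM) and Mctp1 (53.8 and 0.974 CPM). Ppp1r3c (55.8 and 1.35 CPM), the sialyltransferase gene St6galnac1 (168 and 4.74 CPM), Fam169a (261 and 7.74 CPM), the nuclear envelope gene Syne1 (168 and 5.20 CPM), Sphkap (105 and 3.26 CPM), Dsg1a and 1 predicted gene completed that set. Wild-type reference cells held more of Mctp1 (379 CPM) and Syne1 (284 CPM), so that comparison does not distinguish their wild-type levels from free RNA. In the heterozygous library, however, reference levels of 246 and 234 CPM went with 0.974 and 5.20 CPM in the epithelium, so little of that RNA reached it there. With edgeR and DESeq2 factors every epithelial log2 ratio shifted by -0.32 and -0.34, which gave 550 higher and 778 lower genes with the former and 542 and 797 with the latter.

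**Figure D3:**
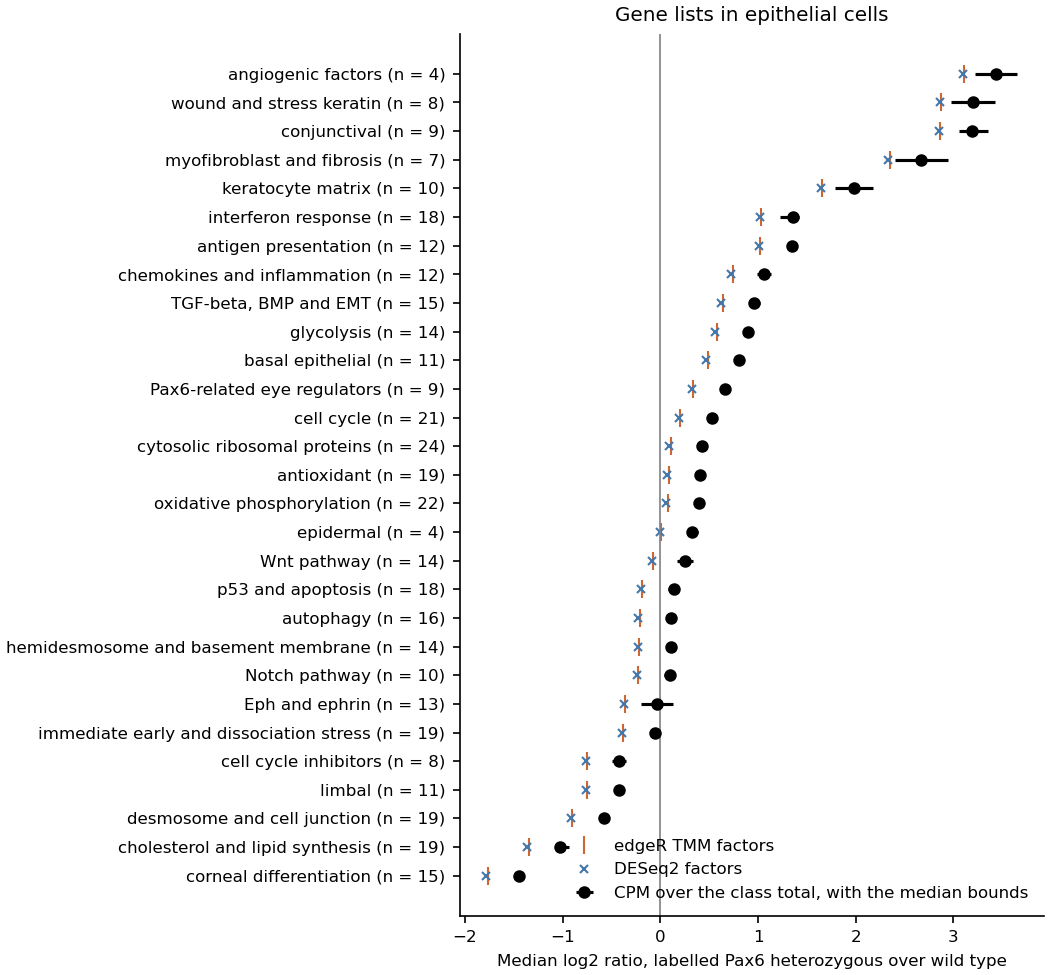
Each black point is the median log2 ratio (x axis, library labelled Pax6 heterozygous over wild type, epithelial cells) of a gene list (y axis, n measured members) with its median bounds from counting error, and marks give the medians with edgeR and DESeq2 factors. Medians ranged from -1.44 for corneal differentiation to 3.43 for angiogenic factors. The epidermal median changed sign under DESeq2 factors, and those of hemidesmosome, Notch, Wnt, autophagy and p53 under both.

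The share of cycling epithelial cells was not clearly different between the libraries in the main count, and the difference depended on how cells were chosen. After thinning, 891 of 7823 wild-type cells (11.4%, 10.7 to 12.1) and 799 of 6424 heterozygous cells (12.4%, 11.6 to 13.3) were cycling, a difference of 1.05 percentage points (-0.474 to 2.58) whose interval spans 0. The difference was 1.92 (0.403 to 3.44) with at least 1000 genes and 2000 UMIs, 1.70 (0.0778 to 3.34) without cluster 17, 1.55 (0.00574 to 3.10) without the 5% highest doublet scores and 4.12 (2.18 to 6.08) with the Xist-only heterozygous cells. The unthinned shares were 19.3% and 25.4%, and with at least 1 UMI over the 6 genes the thinned shares were 18.6% and 21.9%. In reference cells the thinned shares were 3.16% and 1.96%, and 514 wild-type and 379 heterozygous epithelial cells were too shallow to be thinned. Mki67 alone ran the other way, found in 10.6% (9.91 to 11.3) of thinned wild-type and 9.04% (8.35 to 9.77) of thinned heterozygous epithelial cells. Genes of the cell cycle list went both ways: 9 of 21 were at least 2-fold higher and 2 lower (median log2 ratio 0.53, percentile 99.2). The cyclin gene Ccnd2 stood at 179 and 862 CPM and the replication helicase gene Mcm2 at 10.8 and 47.0 CPM, while the mitotic genes Cenpf and Ube2c stood at 91.9 and 38.7 CPM and at 110 and 46.5 CPM.

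Among limbal-like cells, 8 of 15 corneal differentiation genes were at least 2-fold lower in the library labelled Pax6 heterozygous. The limbal list was shifted down as well, though few of its genes were 2-fold apart. The name itself required Gpha2, so its level describes only the cells selected, from different subclusters in each library. Gpha2 stood at 2071 CPM in wild-type and 694 CPM in heterozygous limbal-like cells, a ratio of 0.335 (0.325 to 0.346), and Krt15 at 5267 and 3967 CPM, a ratio of 0.753 (0.739 to 0.768). The basal keratin gene Krt14 stood at 5026 and 6359 CPM, and Pax6 at 417 and 769 CPM, with 436 CPM in subcluster 11 and 1213 CPM in subcluster 22. Of 10 measured limbal genes, 1 was at least 2-fold higher (Ifitm3, also in the interferon response list, 586 and 1561 CPM) and 1 lower (median log2 ratio -0.52, percentile 0.7). Of 11 basal epithelial genes 1 was higher (Bcl11b, 73.0 and 156 CPM) and 0 lower. Of 15 corneal differentiation genes, 0 were at least 2-fold higher and 8 lower (median log2 ratio -1.35, percentile 0.0), with Aldh3a1 at 3345 and 1312 CPM. Reference cells held 2051 and 136 CPM of Aldh3a1, so free RNA could make up more of its wild-type than of its heterozygous level. Krt12 stood at 3077 and 127 CPM and Slurp1 at 70.1 and 1.25 CPM. Their wild-type values were below the 4522 and 380 CPM of wild-type reference cells, so that comparison does not distinguish these members from free RNA. The reference cells were shallower, with a median of 3521 UMIs against 9408 here. Wild-type keratocytes, at a median of 9448 UMIs, held 1520 CPM of Krt12 and 132 CPM of Slurp1. Krt12 in limbal-like cells lay above that keratocyte level and Slurp1 below it. These values compare subcluster 9 with subclusters 11 and 22.

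Limbal-like cells showed the interferon difference as well, together with higher cell cycle and lower junction genes. Of 18 interferon response genes 14 were at least 2-fold higher and 0 lower (median log2 ratio 2.21), and all 11 measured antigen presentation genes were higher (median log2 ratio 1.91), with B2m at 164 and 1051 CPM. Of 19 cell cycle genes, 11 were higher and 1 lower (median log2 ratio 1.11), with Ccnd2 at 646 and 1470 CPM and the mitotic gene Cenpf at 20.5 and 6.87 CPM. Cells of the cycling subclusters were not in this class. After thinning, Mki67 was found in 2.25% (0.735 to 5.18) of wild-type and 2.68% (2.085 to 3.39) of heterozygous limbal-like cells, which were about level. Of 19 desmosome and cell junction genes, 0 were higher and 10 lower (median log2 ratio -1.02), with Dsp at 1783 and 664 CPM. Over all genes, 466 of 7017 were at least 2-fold higher and 318 lower, and scaling moved log2 ratios by at most -0.03.

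By rank, the genes higher in heterozygous limbal-like cells included Ifi44, an interferon-induced gene (1 wild-type UMI, 104 CPM in the heterozygous library, ratio 219, interval 39.2 to 8638). The growth response factor gene Egr4 had 0 wild-type UMIs and was at least 45.5-fold higher, as the lipopolysaccharide-binding protein gene Lbp was at least 42.3-fold and Gbp2b at least 42.2-fold higher. Acta2, a smooth muscle actin gene, had 2 wild-type UMIs and stood at 72.9 CPM in the heterozygous library (ratio 76.5, 21.1 to 632), where reference cells held 1690 CPM. Igfbp4 (5.72 and 141 CPM), Ifi27l2a (15.7 and 225 CPM), the guidance factor gene Sema3e (2.86 and 55.9 CPM), Dapk2 (8.59 and 121 CPM), Ifit1 (6.20 and 87.2 CPM) and 2 predicted genes made up the rest. Heterozygous reference cells held more of Lbp (105 CPM), Gbp2b (221 CPM), Igfbp4 (526 CPM) and Ifit1 (172 CPM), so that comparison does not distinguish these from free RNA. The wild-type reference cells held 41.25, 0, 319 and 49.7 CPM of them, beside 0, 0, 5.72 and 6.20 CPM in wild-type limbal-like cells. Little of the Lbp and Igfbp4 RNA thus reached those cells, whereas Ifit1 stood nearer to its reference level. Lower genes included the cation channel gene Trpm3 (579 and 10.6 CPM), Mgarp (1543 and 53.2 CPM), the adaptor gene Dab1 (112 and 4.67 CPM) and Gna14 (88.7 and 3.60 CPM). Fam169a, at 96.4 and 4.37 CPM, was also lower. Slurp1, Lypd2, Iqgap2, Krt12 and Lsamp were also in this set, but their wild-type values of 70.1, 265, 59.6, 3077 and 141 CPM lay below those of wild-type reference cells, and Gsta2, at 53.4 CPM, lay close to the reference level of 41.2 CPM.

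The few corneal-like cells of the library labelled Pax6 heterozygous differed from those of the wild type in several gene groups. The name itself required Krt12, so cells without it could not enter the class, and the Krt12 level describes only the cells selected. Krt12 stood at 30980 and 21300 CPM, a ratio of 0.688 (0.684 to 0.691), and Aldh3a1 at 10700 and 13260 CPM. Of 15 corneal differentiation genes, 0 were at least 2-fold higher and 6 lower (median log2 ratio -0.70, percentile 0.0), with Slurp1 at 3068 and 380 CPM. Of 21 cell cycle genes, 18 were higher and 0 lower (median log2 ratio 1.94, percentile 100), with the replication factor gene Pclaf at 15.2 and 125 CPM. That list does not compare like cells: cycling wild-type cells with Krt12 were split off into subclusters 0, 5 and 14, while no large heterozygous cycling subcluster held much Krt12 and subclusters 19 and 24 each kept 2 cycling markers. Of 18 interferon response genes 13 were higher and 0 lower (median log2 ratio 2.30), and of 19 cholesterol and lipid synthesis genes 0 were higher and 11 lower (median log2 ratio -1.42), with Lss at 30.7 and 5.73 CPM.

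Single genes differed widely within the corneal-like cells. Krt17 stood at 13.7 and 555 CPM, while Krt6a stood at 2389 and 1018 CPM. Higher by rank were Gbp2b (2 wild-type UMIs, ratio 2023, 556 to 16770), Ndufa4l2 (0.191 and 55.8 CPM), the proteoglycan gene Gpc6 (0.598 and 75.2 CPM), Ly6c1 (0.700 and 72.2 CPM), the potassium channel gene Kcnq5 (2.66 and 232 CPM) and Ly6a (47.2 and 1685 CPM). Ifi44 (4.91 and 273 CPM), Ifi27l2a (17.7 and 782 CPM), the growth factor gene Ptn (5.29 and 180 CPM) and 2 predicted genes followed. Heterozygous reference cells held more of Gbp2b (221 CPM), Ndufa4l2 (175 CPM), Gpc6 (214 CPM) and Ly6c1 (178 CPM), so that comparison does not distinguish these from free RNA. The wild-type reference cells held 0, 80.8, 178.5 and 323 CPM of them, beside 0.0254, 0.191, 0.598 and 0.700 CPM in wild-type corneal-like cells. Little of the Ndufa4l2, Gpc6 and Ly6c1 RNA thus reached the corneal-like cells of that library. Lower were the surface antigen gene Psca (619 and 2.15 CPM), Mpped2 (8433 and 1 UMIs, ratio 0.00134, interval 3.38e-05 to 0.00745), Piezo2 (210 and 2.15 CPM), St6galnac1 (188 and 3.44 CPM), the protease genes Asprv1 (1824 and 59.6 CPM) and Tmprss11d (838 and 43.0 CPM), Necab1 (88.2 and 3.44 CPM) and Enpp3 (116 and 6.31 CPM). Cadm2 (57.9 and 1.86 CPM), Mctp1 (57.7 and 2.87 CPM), Cysrt1 (88.6 and 5.02 CPM) and 1 predicted gene completed the set. Wild-type reference cells held more of Cadm2 (561 CPM) and Mctp1 (379 CPM), so that comparison does not distinguish their wild-type levels from free RNA. In the heterozygous library, however, reference levels of 328 and 246 CPM went with 1.86 and 2.87 CPM in the corneal-like cells. In these cells 674 of 6715 genes were at least 2-fold higher and 432 lower, with 474 and 678 under edgeR factors. The cells came from different subclusters, among them 19 and 24 with 239 and 224 heterozygous cells, and wild-type subclusters 6 and 8 were left out because a limbal marker led them.

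**Figure D4:**
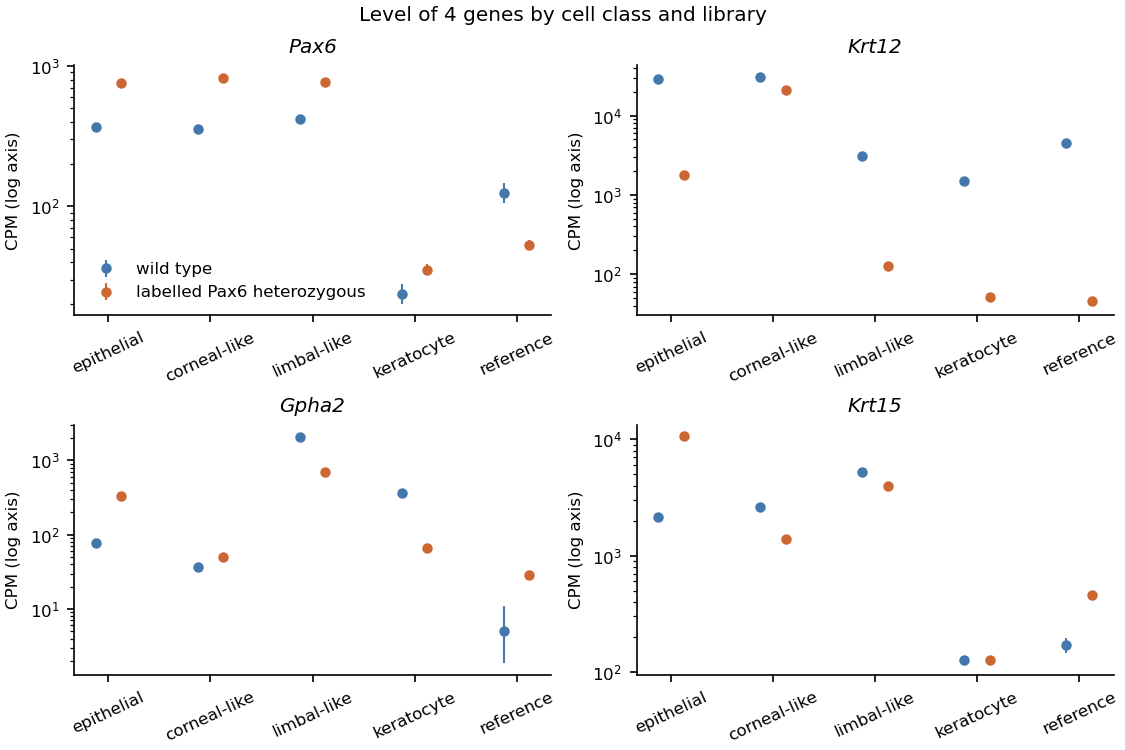
Points give the level of Pax6, Krt12, Gpha2 and Krt15 (y axis, CPM on a log scale) in epithelial, corneal-like, limbal-like, keratocyte and reference cells (x axis) of the wild-type library and the library labelled Pax6 heterozygous, with exact 95% intervals as lines. Pax6 was higher in the heterozygous library in both pooled sub-classes, though level in limbal-like subcluster 11 (436 CPM) and corneal-like subcluster 19 (366 CPM), and Gpha2 in limbal-like cells stood at 2071 and 694 CPM.

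Keratocytes of the library labelled Pax6 heterozygous had higher levels of genes from the fibrosis, inflammation and TGF-beta lists. Xist without any Y-linked UMI was found in 97.4% of wild-type but 21.2% of heterozygous keratocytes. Y-linked UMIs without Xist were found in 0 and 632 of them (64.4%). The keratocyte comparison was not repeated with Xist-only cells, so sex cannot be told apart from genotype in it. Of 15 myofibroblast and fibrosis genes, 9 were at least 2-fold higher and 0 lower (median log2 ratio 1.63, percentile 100). The secreted phosphoprotein gene Spp1 stood at 3.38 and 65.1 CPM, the matrix protease gene Mmp3 at 458 and 883 CPM, Tnc at 20.8 and 228 CPM and the collagen gene Col8a1 at 24.9 and 314 CPM. Of 14 chemokine and inflammation genes, 8 were higher and 1 lower (median log2 ratio 1.07, percentile 100), with the cytokine gene Il6 at 3.38 and 49.1 CPM. Of 19 TGF-beta, BMP and EMT genes, 6 were higher and 1 lower (median log2 ratio 0.74, percentile 100), with Tgfb1 at 25.7 and 135 CPM, Sparc at 12140 and 30340 CPM and the transcription factor gene Twist1 at 860 and 333 CPM. Reference cells held more Il6 (237 and 781 CPM) and Tnc (37.0 and 437 CPM) than keratocytes in both libraries, and Tgfb1 stood at 66.5 and 123 CPM there, so these are not distinguished from free RNA, whereas Mmp3, Sparc and Twist1 lay above the reference in both. Cluster 30, which holds most heterozygous keratocytes, also had 1 iris, ciliary or trabecular marker among its 10 leading genes.

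The matrix genes of keratocytes differed in both directions. Of 20 keratocyte matrix genes, 6 were at least 2-fold higher and 1 lower (median log2 ratio 0.17). Collagen I genes stood higher, with Col1a1 at 8236 and 29730 CPM and Col1a2 at 9638 and 24960 CPM, while keratocan (Kera), a proteoglycan of the clear stroma, stood at 9062 and 4672 CPM and the keratan sulfate enzyme gene B3gnt7 at 146 and 29.4 CPM. Dcn was nearly level at 33900 and 34300 CPM. The VEGF receptor gene Kdr stood at 196 and 37.7 CPM, below reference levels of 253 and 223 CPM and so not distinguished from free RNA. Vegfa stood at 55.3 and 149 CPM, the Wnt inhibitor gene Dkk2 at 1462 and 473 CPM and the antioxidant enzyme gene Hmox1 at 8.97 and 167 CPM. Gpha2 stood at 364 and 66.5 CPM, against 5.05 and 28.8 CPM in reference cells.

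By rank, the genes higher in heterozygous keratocytes were Cryaa, a lens crystallin gene with 0 wild-type UMIs that was at least 143-fold higher, the complement protease genes C1s2 (1 wild-type UMI, ratio 313, 56.0 to 12390) and C1rb (3 UMIs, ratio 114, 39.0 to 556), Pianp (2 UMIs, ratio 156, 43.0 to 1290) and Olfm2 (3.21 and 132 CPM). Cryaa was among the 10 leading genes of cluster 11, and reference cells of the heterozygous library held 0.384 CPM of it. Lower were Cadps (139 and 1.30 CPM) and the serotonin receptor gene Htr5b (72.9 and 0.994 CPM), and also Slurp1, Lypd2 and Krt12, whose wild-type values of 132, 175 and 1520 CPM lay below the wild-type reference. Epithelial lists were lower too: 10 of 15 corneal differentiation genes (median log2 ratio -2.38) and 13 of 17 desmosome genes (-2.56) were at least 2-fold lower. Dsc3, at 60.2 and 4.05 CPM, lay below reference levels of 168 and 12.5 CPM, whereas Aldh3a1, at 3673 and 1860 CPM, lay above its reference levels of 2051 and 136 CPM. Over all genes, 580 of 7081 were at least 2-fold higher and 455 lower, with 743 and 289 under edgeR factors. Within the library-specific clusters 566 of 6982 genes were higher and 608 lower, with 783 and 302 under edgeR factors. Most of the class came from different clusters, 14 with 561 wild-type and 2 heterozygous cells, 30 with 1 and 605, and 11 with 92 and 375.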

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

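Apart from the edgeR and DESeq2 scaling, which was planned, the tests in this part were chosen after the result they concern was seen. Barcodes left out by the cell filters held haemoglobin transcripts in the library labelled Pax6 heterozygous. They came to 11770 of 1451154 UMIs in 1054 barcodes, or 0.811% (0.797 to 0.826), and in 6 of those barcodes most UMIs were haemoglobin. The wild-type library had 0 of 912056 UMIs in its 1202 barcodes left out, with an upper limit of 0.000404%. What drew attention to it was a signal, in barcodes that no comparison uses, above the limit that a count of 0 allows. Among kept cells there were 17 and 93 haemoglobin UMIs. Red blood cells in the suspension were not weighed against other sources, and no biological explanation was tested.

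The first pattern weighed was the low Krt12 of the heterozygous epithelium. Free Krt12 RNA in the wild-type suspension was argued against as the whole source, since wild-type epithelial cells held 6.49 times the level of reference cells. The sex of the mice was argued against too, since the ratio was 0.0895 with the Xist-only heterozygous cells. More limbal and conjunctival tissue left by the dissection could not be excluded: 91.0% of heterozygous epithelial cells held fewer than 20 Krt12 UMIs per 10000, a value that a loss of Krt12 from corneal cells and a larger share of non-corneal tissue would both give. These cannot be told apart with 1 dissection per genotype, and the genotype stays among the open explanations.

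The second pattern was the higher Pax6 of the library labelled Pax6 heterozygous. A different mix of epithelial cell types stays open: over wild-type corneal-like cells the ratio was 1.03 (0.979 to 1.08) in heterozygous subcluster 19 and 4.77 (4.61 to 4.93) in subcluster 24. Scaling was argued against, because the lowest ratio with edgeR or DESeq2 factors was 1.63. An exchange of the library labels cannot be told apart from a real difference in transcript level: the ratio of 2.06 has the direction an exchange would give, limbal-like subcluster 11 was level with the wild type at 1.05 (0.974 to 1.12), and no allele description or transcript sequence in the counts says which library carries the mutation. Higher transcript from a mutant or compensating allele stays open and was not tested.

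The third pattern was a set of genes at least 5-fold apart in the same direction in epithelial cells, keratocytes and reference cells. Among 7479 genes compared, 10 were higher and 18 lower in the library labelled Pax6 heterozygous. For the higher genes, among them Tnc, Medag and Rnaset2a, the median reference level was 0.672 (0.201 to 0.881) of the epithelial level, while Krt12 showed 0.0259. That median cannot decide on free epithelial RNA, because a gene needed at least 10 CPM in the reference cells to enter. Genes with low epithelial levels thus lay above the Krt12 share by the way they were chosen. Krt17 (0.0563) and Krt4 (0.0327), which had high epithelial levels, lay near the Krt12 share, and free RNA stays open for them. For the lower genes free epithelial RNA may account for the reference levels, with a median of 0.186 (0.146 to 0.231) beside 0.154 for Krt12, except Trim12a (1.62), Rpl29 (0.462) and A830036E02Rik (0.333). That check covered reference cells only. Wild-type keratocytes held 237 CPM of Fam169a and 119 CPM of Ahnak2, against 261 and 215 CPM in the epithelium. For Krt12 these levels were 1520 and 29400 CPM, so free epithelial RNA does not account for the keratocyte levels of Fam169a and Ahnak2. Sex was argued against for epithelial cells only, where 27 of the 28 genes kept their difference with the Xist-only cells, and a difference in genetic background cannot be told apart from the genotype, as the genes lie on 11 chromosomes and the labels give no strain.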

How the results depend on the processing

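The settings without cluster 17, without subcluster 12, without the 5% highest doublet scores and with the Xist-only heterozygous cells were chosen after seeing the data, and the other alternatives were planned. Of 142 values recomputed for 11 results, 67 stayed within the counting interval or, for gene counts, within 1.5 times the main count, 75 moved beyond it and 0 reversed direction. Gene counts could not be labelled reversed, because each count has no direction of its own. Their balance did turn over, from 931 higher and 453 lower to 550 and 778 with edgeR and 542 and 797 with DESeq2 factors. The counting intervals are narrow, so most moves were small. No paired analysis was possible because the labels give 1 library per genotype and no pairing.

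Over the alternatives the Pax6 ratio ranged from 1.63 to 2.33, the Gpha2 ratio from 3.42 to 4.98, the Krt15 ratio from 3.92 to 6.16 and the Krt12 ratio from 0.0480 to 0.0895. The difference in epithelial share ranged from -19.9 to -1.54 percentage points and that in limbal-like share from 22.2 to 43.2. The cycling difference ranged from 0.942 to 6.11 points. The cause was not tested for the moves below, unless stated.

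With at least 200 genes and 500 UMIs, the Pax6 ratio was 2.02, the Krt15 ratio 5.03, the Krt12 ratio 0.0611, the limbal-like difference 39.9 points and the limbal list median -0.41. With at least 1000 genes and 2000 UMIs, the Pax6 ratio was 2.02, the Krt15 ratio 5.03, the Krt12 ratio 0.0610 and the epithelial difference -15.5 points. With at most 10% mitochondrial UMIs, the ratios were 1.97 for Pax6, 4.45 for Gpha2, 5.07 for Krt15 and 0.0615 for Krt12, the epithelial difference was -19.9, the limbal-like difference 41.3 and the limbal median -0.40. Without doublet removal the Krt15 ratio was 4.98.

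At Leiden resolution 0.5 the ratios were 2.02 for Pax6, 5.05 for Krt15 and 0.0612 for Krt12, the epithelial difference was -18.6, the limbal-like difference 41.5 and the limbal median -0.41. At resolution 2.0 the Pax6 ratio was 2.01, the Krt15 ratio 5.04 and the epithelial difference -14.5. With each library clustered alone the limbal-like difference was 22.2 and the Krt15 ratio 5.00. With clustering, but not naming, that left out the limbal genes and Pax6, the limbal-like difference was 40.0.

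With edgeR factors the ratios were 1.65 for Pax6, 3.46 for Gpha2, 3.96 for Krt15 and 0.0485 for Krt12, and 550 genes were higher and 778 lower. The limbal median was -0.75 and the corneal differentiation median -1.77. With DESeq2 factors they were 1.63, 3.42, 3.92 and 0.0480, with 542 and 797 genes and medians of -0.76 and -1.78. A single factor per library shifts every ratio alike, which is the cause of these moves. With the mean of per-cell CPM, the ratios were 2.33, 3.72, 6.16 and 0.0581, and the medians -0.36 and -1.42.

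With a minimum of 5 CPM, 1743 genes were higher and 698 lower, because more genes were counted. Without a CPM minimum the medians were -0.34 and -1.73. The cycling difference was 6.11 points with unthinned UMIs, where deeper cells pass more easily, and 3.28 points with at least 1 UMI over the 6 genes.

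Without the 5% highest doublet scores the limbal-like difference was 43.2, because the wild-type limbal cluster lost its name and its share was 0.0126%, the Krt15 ratio was 4.89 and the Krt12 ratio 0.0601. Without cluster 17 the ratios were 2.24 for Pax6, 4.98 for Gpha2, 4.46 for Krt15 and 0.0662 for Krt12. The epithelial difference was then -13.4, the limbal-like difference 42.6 and the medians -0.48 and -1.50. With the Xist-only heterozygous cells the Pax6 ratio was 2.23 and the Krt12 ratio 0.0895. The epithelial difference was then -1.54, with an interval of -3.48 to 0.377 that spans 0, the limbal-like difference 28.4, the cycling difference 4.12 (2.18 to 6.08) and the medians -0.59 and -1.42. Wild-type cells were not filtered for Xist in this setting, so part of the change in epithelial share may come from the unequal filter.

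Depth limits the shallow classes most: reference cells held 1187869 UMIs in the wild-type library against 10404823 in the heterozygous library, and wild-type limbal-like cells 2096366 against 32755425. A wild-type count of 0 there bounds a ratio less tightly than one in the epithelium.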

Other observations

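The tests behind these values were descriptive, and the split by sex-linked transcripts was made after seeing the data. The sexes of the heterozygous library differed in composition. Among cells with Xist and no Y-linked UMI, corneal-like cells made up 10.2% (9.27 to 11.3) of the epithelium, against 2.58% (2.00 to 3.28) of cells with Y-linked UMIs and no Xist, and limbal-like cells, here without subcluster 12, 30.2% (28.7 to 31.7) against 49.4% (47.5 to 51.4). Conjunctival-like cells made up 43.5% against 35.4%, and cycling clusters 13.3% against 8.22%. Keratocytes were 4.72% against 16.9% of these kept cells, mural cells 5.29% against 6% and vascular endothelial cells 3.58% against 3.07%. The number of mice behind each sex is not given, so these may be differences between single animals, and the Krt12 ratio was 0.0895 with the Xist-only cells.

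Regulators and receptors of the epithelium also differed. Of 9 Pax6-related eye regulators, 3 were at least 2-fold higher and 0 lower in the heterozygous epithelium (median log2 ratio 0.66, percentile 98.8), with the AP-2 factor genes Tfap2b at 5.36 and 102 CPM and Tfap2a at 68.4 and 45.7 CPM. Of 11 basal epithelial genes, 5 were higher and 0 lower (median 0.81, percentile 99.9), with Krt5 at 6759 and 4255 CPM and the zinc finger gene Bcl11b at 12.5 and 122 CPM. Of 13 Eph and ephrin genes, 2 were higher and 1 lower (median -0.04), with the receptor gene Ephb2 at 4.32 and 70.2 CPM. Of 8 cell cycle inhibitors, 1 was higher and 1 lower (median -0.42, percentile 1.4), with Cdkn1c at 4.82 and 22.7 CPM and Cdkn2b at 33.1 and 13.9 CPM.

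Signalling and stress lists held genes in both directions. Of 10 Notch genes, 1 was higher and 0 lower, with Jag2 at 50.8 and 102 CPM, and the median of 0.10 changed sign under edgeR (-0.23) and DESeq2 (-0.24) factors. Of 14 Wnt genes, 3 were higher and 3 lower, with Wnt6 at 10.0 and 28.4 CPM and Dkk3 at 178 and 65.2 CPM, and the median of 0.25 changed sign under both (-0.07 and -0.08). Of 16 autophagy genes, 1 was higher and 1 lower, with Map1lc3a at 97.4 and 215 CPM, and the median of 0.11 changed sign under both (-0.21 and -0.22). Of 18 p53 and apoptosis genes, 2 were higher and 0 lower, with Cdkn1a at 807 and 410 CPM, and the median of 0.14 changed sign under both (-0.19 and -0.20). Of 19 immediate early and dissociation stress genes, 2 were higher and 2 lower (median -0.06), with Nr4a1 at 98.9 and 257 CPM and Zfp36 at 1502 and 556 CPM. Of 19 antioxidant genes, 5 were higher and 2 lower (median 0.41), with the cystine transporter gene Slc7a11 at 1.03 and 20.5 CPM and Gsta4 at 5701 and 2125 CPM.

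Among epithelial cells outside the limbal-like class, 849 of 7054 genes were at least 2-fold higher and 432 lower, with 533 and 710 under edgeR factors. The limbal list had a median log2 ratio of -0.71 there (4 of 11 higher, 4 lower), the corneal differentiation list -1.39 (0 of 15 higher, 8 lower) and the conjunctival list 3.86 (7 of 9 higher, 1 lower).

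Library-specific keratocyte clusters gave the myofibroblast and fibrosis list a median log2 ratio of 1.86, with 10 of 15 genes higher and 0 lower, and the Wnt list -0.78, with 1 of 14 higher and 4 lower. Of these cells 98.6% of the wild-type and 18.1% of the heterozygous ones held Xist without a Y-linked UMI, so sex was not separated from genotype. By rank, the protease inhibitor gene Timp1 had 0 wild-type UMIs and was at least 105-fold higher. Reference cells of the heterozygous library held 85.3 CPM against 58.8 CPM here, so that comparison does not distinguish Timp1 from free RNA. Wild-type reference cells held 23.6 CPM of it, so little of that RNA reached the keratocytes of that library. Bcat1 was at least 91.5-fold higher, and Chil1, a secreted chitinase-like protein gene, stood at 1.68 and 260 CPM.

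The nuclear transcript Gm42418, which overlaps a ribosomal RNA locus, took 21.1% of UMIs in the barcodes left out of the wild-type library and 3.13% in those left out of the heterozygous library, and 3.26% and 1.10% in kept cells.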
